A study of Homo sapiens with 6 samples.

How the data were processed

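Forebrain neurons derived from H9 human embryonic stem cells were collected at day 26, and total-cell, cytoplasmic and nuclear RNA were sequenced in 2 replicates each, per the labels. Ribosomal RNA was depleted and stranded total RNA libraries were made and sequenced on a NovaSeq instrument, per the labels' protocols. The submitters' processing notes name Trimmomatic 0.39, HISAT2 2.1.0, SAMtools 1.9, featureCounts 2.0.1 and Bowtie and the builds GRCh38 and hg38, without saying what each was used for. The tool that called back-splice junctions, the annotation release, the strand setting and the treatment of overlapping genes are not given in the sources used here.

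Gene levels are FPKM, fragments scaled by transcript length and library size, computed by the authors, per the file headers. The table described as mRNA held all gene types, of which 19729 genes were taken as protein-coding by their RefSeq type or, failing that, their GENCODE v29 type. Of 9480 lncRNAs with values to compare in both FPKM tables, 43.2% had the same value within 2% and 12.8% had double, so the tables were not counted in the same way, and tests were made only within a table. CircRNA levels are a signal in FPB deposited by the authors, per the file headers, read here as fragments scaled by mapped bases, a meaning not given in the sources used here. All FPB values of each library were whole multiples of its smallest value (100% within a tolerance of 0.05 reads), so whole reads were recovered. The limit that 0 reads allows, taken as 3 reads, was 0.150 and 0.144 FPB in the cytoplasmic, 0.247 and 0.203 FPB in the nuclear and 0.369 and 0.296 FPB in the total-cell libraries. Intervals and floors cover counting error only. The circRNA reads of replicates differed beyond sampling noise in the cytoplasm (chi-square per degree of freedom 1.63, p = 2.5e-26) and in total RNA (1.73, p = 2.5e-19), so these intervals understate the spread there. The reads of the nuclear replicates did not pass that test (chi-square per degree of freedom 1.18, p = 0.0575), but their mapped bases and gene values differed, so they were counted as 2 libraries. The circRNA table also had 7 blank lines, which were skipped.

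CircRNA positions were given with a start counted from 0. Starts are printed counted from 1, and 30871 of them then fell on an exon start and 30911 ends on an exon end of GENCODE v29 (hg38). Sequence and exon number were reconstructed for 30237 circRNAs from the annotated transcript with both ends, with all exons between them kept, which the back-splice reads do not show.

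Values were tested as log2(value + pseudocount) with limma 3.58.1 (R 4.3.3), with an intensity trend, in a one-way model of the 3 fractions over all 6 libraries (3 residual degrees of freedom) and Benjamini-Hochberg adjustment at 0.05. The pseudocount was 1 FPKM for mRNAs and lncRNAs and 0.123 FPB for circRNAs, and features were tested when their mean over the 6 libraries reached 1 FPKM, 0.3 FPKM and 0.369 FPB. A log2 fold change on this scale understates the change of features with low levels. For mRNAs limma estimated an infinite prior degree of freedom, so each mRNA took its spread wholly from the trend and very small p-values rest on that assumption. Counts with each feature's own spread were therefore added. Changes of 2-fold and 4-fold were simulated on the scale of value + pseudocount, with spreads shuffled over features. The cytoplasm and nucleus contrast recovered 94% and 100% of them for mRNAs (10236 tested, 200 changed, 4 false calls). Recovery was 91% and 99% for lncRNAs (4540 tested, 200 changed, 11 false calls) and 13.2% and 71.4% for circRNAs (914 tested, 182 changed, 0 false calls). A 2-fold change of a feature near the filter is smaller on this scale, so its recovery was not measured. The rates are also not comparable between classes, since the changed shares differed. edgeR 4.0.16 (quasi-likelihood) was run on the recovered circRNA reads as an alternative.

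Before the data were examined, 19 gene lists, the tests, the alternatives and the naming rule were fixed. Named features are the 8 largest rises and falls per class between cytoplasm and nucleus among called features with a mean of at least 5 times the filter and the same sign in both replicates, the 4 best-expressed members of each list, the 8 circRNAs with the highest mean, and the circRNAs of HIPK3, ZNF609, SMARCA5 and CDR1-AS by position. Some features that this rule names are not reported here. Members of a list that were called lower in the cytoplasm and a few circRNAs were named in addition after their values were seen. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01 and again with an estimated correlation. Correlations across features have two-sided p-values from 100000 permutations. Alternatives were the pseudocount, the filter, each library left out, libraries scaled to one median (circRNAs by the mRNA factors), limma without trend, only the cytoplasmic and nuclear libraries, and a block for the replicate number. The scaling factors of mRNAs and of lncRNAs each came from the tested features of that class. After seeing the data, lncRNAs without overlap, all gene types, each feature's own spread, further forms of the A content relation, other pseudocounts for the host gene comparison and scaling of the count above both fractions were added.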

Results

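RNA was measured in forebrain neurons differentiated from the human embryonic stem cell line H9 and collected at day 26. Total-cell RNA, cytoplasmic RNA and nuclear RNA were each sequenced in 2 replicates, 6 libraries in all. The deposited tables gave FPKM for genes and FPB for circular RNAs (circRNAs), which are closed RNA rings recognised by reads across a back-spliced exon junction. Back-splice reads numbered 46002 and 52244 in the cytoplasmic libraries, 13338 and 15395 in the nuclear libraries and 26114 and 33318 in the total-cell libraries. If FPB is read as fragments per Gb of mapped bases, the steps of its values correspond to 20.1 and 20.8 Gb in the cytoplasmic libraries, 12.1 and 14.7 Gb in the nuclear libraries and 8.12 and 10.2 Gb in the total-cell libraries. The FPKM tables gave no read counts, so the depth behind single genes is unknown. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

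The cytoplasm and nucleus were compared first for protein-coding mRNAs, to ask which messages were relatively enriched in each compartment. Mitochondrially encoded mRNAs had the largest cytoplasmic excess. MT-CO2, a subunit of cytochrome c oxidase, stood at 1906 ± 342 FPKM (SD, n = 2) in the cytoplasm and 150 ± 5.65 FPKM in the nucleus, a log2 fold change of 3.65 ± 0.14 (limma SE). The other leading genes were MT-ND3 (3.52), MT-CO3 (3.46), MT-ATP8 (3.44), MT-ND1 (3.26), MT-ATP6 (3.16), MT-CO1 (3.11) and FTH1 (3.03), which encodes the ferritin heavy chain and lies on chromosome 11 from 61959718 to 61967660 (hg38). FTH1 measured 166 ± 3.94 FPKM in the cytoplasm and 19.4 ± 0.397 FPKM in the nucleus.

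MAP1B, a microtubule-associated protein gene on chromosome 5 from 72107234 to 72209570, measured 13.7 ± 0.921 FPKM in the cytoplasm and 53.3 ± 6.64 FPKM in the nucleus (log2 fold change -1.88 ± 0.13, limma SE). CKAP5, another microtubule-associated protein gene, fell by 1.09 on the log2 scale, DBN1, which encodes the actin-binding protein drebrin, by 1.05, and SPTBN1, a spectrin gene, by 1.03. PRRC2C and the dynein heavy chain gene DYNC1H1 both fell by 0.83. AC090227.1 also fell by 1.88, but its annotated span overlaps the small nucleolar RNA host gene SNHG22 on the opposite strand, and its reads may be shared because the strand setting of the counting is not stated.

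As deposited, 9220 of 10236 tested mRNAs were higher in the cytoplasm and 129 lower (limma, adjusted p below 0.05), with a median log2 fold change of 0.82. After the libraries were scaled to one median, 4099 were higher and 3415 lower and the median was 0.03, so the groups of genes below are described relative to the median. The 129 lower ones became 85 without cytoplasm replicate 1, 72 without cytoplasm replicate 2 and 62 without nucleus replicate 2, and with each mRNA's own spread 8510 were higher and 72 lower. Examples whose sign depended on the scaling are given with their scaled value.

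**Figure D1:**
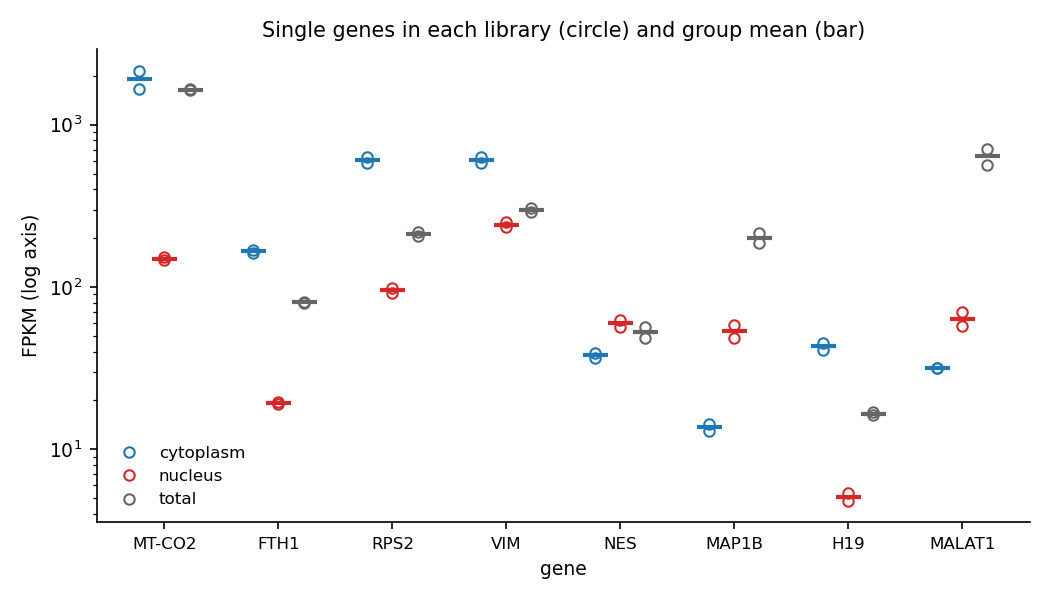
FPKM on a log axis of 8 named genes in each library (open circles, 2 per group) with the group mean (bar), for cytoplasm, nucleus and total cell. MT-CO2, FTH1, RPS2, VIM and H19 lay higher in both cytoplasmic than in both nuclear libraries, and NES, MAP1B and MALAT1 lower.

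Messages of the translation and respiration machinery had higher cytoplasm-to-nucleus ratios than the median mRNA. Over mRNAs this ratio fell with exon length (rho = -0.512), and no list was compared with mRNAs of like length for it. Length and function are therefore not separated for the genes above and the lists below. Of 82 ribosomal protein mRNAs, 81 rose and 1 fell (80 and 2 after scaling), with a median 1.58 above that of all mRNAs (camera adjusted p = 3.3e-50, and adjusted p = 0.433 with an estimated correlation). RPS2 rose from 95.6 ± 4.92 to 603 ± 34.7 FPKM, and the exception, named after its value was seen, was RPS29 (log2 fold change -0.29, limma adjusted p = 0.0259). All 13 mitochondrially encoded mRNAs rose under both scalings, with a median 2.29 above that of all mRNAs (camera adjusted p = 8.4e-31, and adjusted p = 0.281 with an estimated correlation). Of the 84 nuclear-encoded respiratory chain mRNAs, 84 rose as deposited and 82 after scaling, among them COX8A (2.38), UQCRH (2.33) and NDUFS5 (2.27) (camera adjusted p = 2.3e-30, and adjusted p = 0.488 with an estimated correlation). All 65 tested histone mRNAs rose under both scalings, with a median 1.62 above that of all mRNAs (camera adjusted p = 2.7e-53, and adjusted p = 0.281 with an estimated correlation). H4C11 reached 1711 ± 75.1 FPKM in the cytoplasm against 248 ± 25.8 FPKM in the nucleus, and H1-4, H2BC12 and H2AC8 had log2 fold changes of 2.15, 2.49 and 2.31. Histone and ribosomal protein genes have near-identical copies or processed pseudogenes, so the values of single members are uncertain. Adjusted over the list alone, the calls in these lists numbered 82, 13, 84 and 65, as over all genes.

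Zinc finger and secretory messages lay on the nuclear side of the median. Among 285 zinc finger (ZNF) mRNAs, 232 rose, 1 (ZNF692) fell and 52 were not called, but after scaling 26 rose and 158 fell (camera down, adjusted p = 1.0e-07, and adjusted p = 0.908 with an estimated correlation). Their best-expressed members were ZNF428 (1.59), ZNF532 (0.95, and -0.14 after scaling), ZNF664 (1.07) and ZNF462 (0.12, limma adjusted p = 0.366, not called, and -0.94 after scaling). Of 27 mRNAs for ER chaperones and secreted or membrane proteins, 15 rose, 6 fell and 6 were not called, against 3 higher and 22 lower after scaling (camera down, adjusted p = 6.1e-06, and adjusted p = 0.908 with an estimated correlation). The fallers were FN1 (-0.82), COL4A1 (-0.43), COL4A2 (-0.46), COL4A5 (-0.36), LAMB1 (-0.44) and HSP90B1 (-0.44). HSPA5, an ER chaperone gene, measured 48.0 ± 1.22 FPKM in the cytoplasm and 45.3 ± 6.50 FPKM in the nucleus and was not called (-1.08 on the log2 scale after scaling), while SPARC rose by 1.19 on the log2 scale. Of 16 tested mRNAs from very long neuronal adhesion and synaptic genes, 9 rose, 0 fell and 7 were not called, and after scaling 0 rose and 10 fell (camera down, adjusted p = 1.1e-04, and adjusted p = 0.870 with an estimated correlation). CNTNAP2 rose by 1.10, and PTPRD had a log2 fold change of -0.23 (limma adjusted p = 0.0659). Of 23 splicing factor and kinase mRNAs with detained introns, 14 rose, 2 (CCNL2 and NKTR) fell and 7 were not called, against 6 higher and 16 lower after scaling (camera down, adjusted p = 0.0465, and adjusted p = 0.908 with an estimated correlation). The median of that list lay at -0.04 relative to that of all mRNAs, close to it, although camera pointed down. SRSF3 and SRSF7, both splicing factor genes, each rose by 1.65. Adjusted over the list alone, the calls in these lists numbered 232, 21, 9 and 16.

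Lists of cell identity did not stand apart as sets. All 17 forebrain progenitor mRNAs were called, 13 higher and 4 lower, and after scaling 4 were higher and 5 lower (camera adjusted p = 0.342). VIM rose from 242 ± 13.2 to 606 ± 33.2 FPKM, and SOX2 rose by 1.02 (-0.13 after scaling). NES, which encodes the intermediate filament nestin, fell (-0.64 ± 0.13, limma adjusted p = 1.9e-06), as did MKI67 (-1.03), TOP2A (-0.51) and NOTCH1 (-0.35). The median of that list lay 0.21 above that of all mRNAs, whereas camera pointed down. All 14 tested neuron markers rose, and after scaling 5 rose and 2 fell (camera adjusted p = 0.652), with GAP43 at 1.57, STMN2 at 1.82, STMN1 at 1.99 and TUBB3 at 1.59. Of 6 interneuron and ventral forebrain mRNAs 5 rose, against 2 higher and 3 lower after scaling (camera adjusted p = 0.919). DLX5 rose by 1.27 and DLX2 by 1.49, while DLX1 (0.94) turned to -0.17 after scaling. All 13 immediate early mRNAs rose as deposited, and 2 rose and 9 fell after scaling (camera adjusted p = 0.310). Their best-expressed members were EGR1 (1.07, and -0.01 after scaling), DUSP1 (0.80, and -0.26), JUN (0.38, and -0.69) and ATF3 (1.34). Of 16 mRNAs for poly(A)-binding proteins and RNA export factors, 15 rose and TPR fell (-0.75), against 5 higher and 6 lower after scaling (camera adjusted p = 0.919). PABPC1, the cytoplasmic poly(A)-binding protein gene named in the series title, measured 60.9 ± 4.81 FPKM in the cytoplasm, 22.5 ± 2.22 FPKM in the nucleus and 61.6 ± 6.95 FPKM in total RNA. Adjusted over the list alone, the calls in these lists numbered 17, 14, 5, 13 and 16.

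None of 10 glial and none of 12 hindbrain or spinal cord markers passed the expression filter, so 0 members of either list were tested. LIN28A, DNMT3B and DPPA4 were the 3 pluripotency markers tested, all higher in the cytoplasm (1 higher and 0 lower after scaling), at 5.26 ± 0.819, 4.02 ± 0.457 and 1.503 ± 0.195 FPKM in total RNA. Of 6 mesenchymal, vascular or neural crest markers, TAGLN (1.83) and ACTA2 (1.76) rose, COL3A1 fell (-0.37) and 3 were not called, against 2 higher and 4 lower after scaling (camera adjusted p = 0.128). COL3A1 measured 24.8 ± 3.67 FPKM and COL1A1, which was not called (0.06, and -1.02 after scaling), 5.99 ± 0.911 FPKM in total RNA. Adjusted over the list alone, the calls in the last 2 lists numbered 3 and 3.

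**Figure D2:**
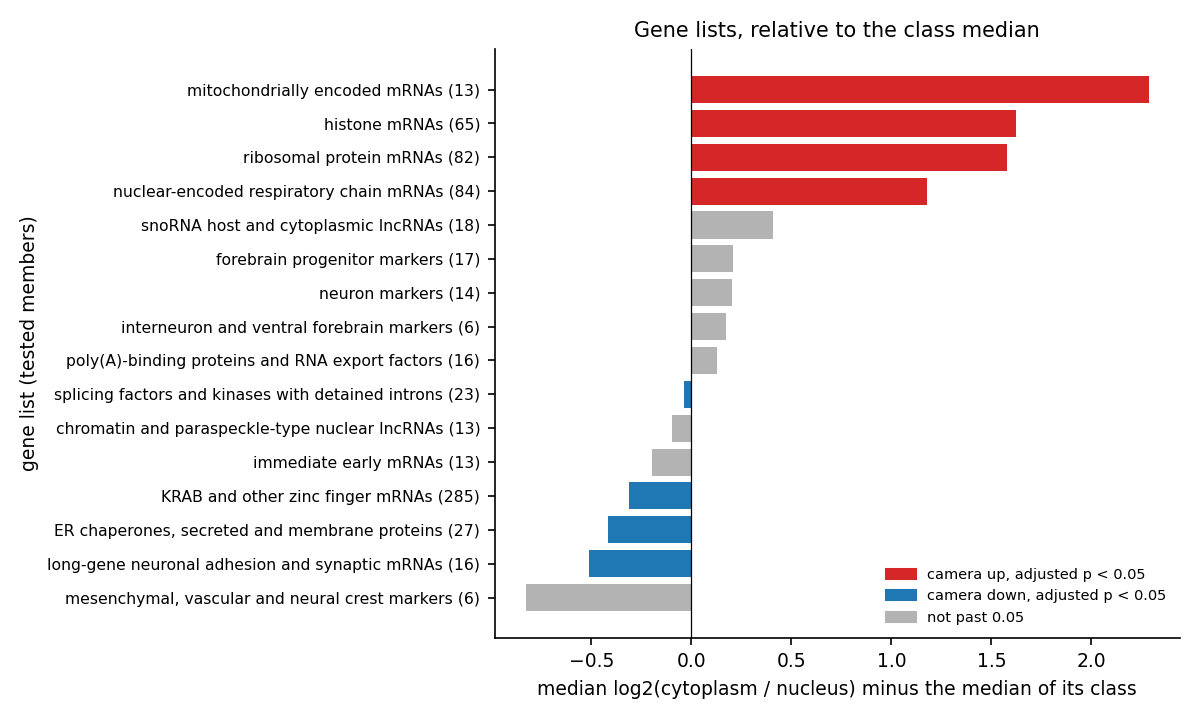
Median log2(cytoplasm/nucleus) of each gene list with at least 5 tested members (bars, members in parentheses), minus the median of its class. The 4 lists called up by camera lay between 1.18 and 2.29 above the median, and the colours mark calls made with the preset correlation, none of which passed with an estimated one.

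Long noncoding RNAs (lncRNAs) were compared in the same way. H19, an imprinted lncRNA on chromosome 11 from 1995176 to 2001470, measured 43.1 ± 2.88 FPKM in the cytoplasm and 5.08 ± 0.377 FPKM in the nucleus (log2 fold change 2.86 ± 0.13, limma SE, adjusted p = 7.7e-05). MALAT1, a lncRNA known for nuclear speckles, measured 31.5 ± 0.039 FPKM in the cytoplasm and 63.8 ± 8.93 FPKM in the nucleus (-0.99 ± 0.18, limma adjusted p = 0.00273). MIR17HG, the host of a microRNA cluster on chromosome 13, fell from 3.06 ± 0.331 FPKM in the nucleus to 0.525 ± 0.0447 FPKM in the cytoplasm, a log2 fold change of -1.41.

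Many of the other lncRNAs with large changes shared their position with a different kind of gene. Among the risers, AL355075.4 (3.41) overlaps RPPH1, the RNA of RNase P, AL138963.3 (2.58) TPT1 and AP003352.1 (2.35) RPL30. AC112491.1 (2.53) and AC005062.1 (2.50) overlap pseudogenes of ribosomal protein genes, and AC004882.3 (2.37) had no gene of that symbol in GENCODE v29. Among the fallers, AL356488.2 (-2.92) overlaps SCARNA2 and AC006064.5 (-2.92) SCARNA10, which are small Cajal body RNAs, as is SCARNA9 (-2.24) itself. AC007952.4 (-1.79) overlaps SNORD3D, SNHG22 (-1.45) spans SCARNA17, and AC124312.3 (-1.29) spans 2 small nucleolar RNAs of the SNORD116 family. The entry hsa-mir-423 (-1.91) overlaps the microRNA gene MIR423. The values of all these entries are uncertain, since the treatment of overlapping genes and strand is not stated.

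In total, 2009 of 4540 tested lncRNAs were higher in the cytoplasm and 62 lower (limma, adjusted p below 0.05), against 876 and 546 after scaling, and the median moved from 0.26 to -0.01. The scaling used factors from the lncRNAs themselves, which fixes their median in advance. Without nucleus replicate 1 the count of calls went from 2071 to 1275, and the 62 lower ones became 36 and 37 without cytoplasm replicate 1 or 2, 35 and 30 without nucleus replicate 1 or 2, 146 with a pseudocount of 0.1 FPKM and 125 with only the libraries of both fractions. Each lncRNA's own spread gave 1308 higher and 36 lower. The usual limma fit of only the 1834 lncRNAs without exonic overlap with a protein-coding gene gave 376 calls, 356 higher and 20 lower. Of 13 lncRNAs listed for nuclear or chromatin roles, 5 rose, MALAT1 fell and 7 were not called, against 4 higher and 3 lower after scaling (camera adjusted p = 0.574). RMST, a neurogenic lncRNA, rose from 1.78 ± 0.241 to 12.1 ± 0.691 FPKM and DLX6-AS1 from 1.49 ± 0.208 to 2.27 ± 0.00123 FPKM (-0.17 on the log2 scale after scaling), while MIAT measured 1.20 ± 0.00306 FPKM in the cytoplasm and 1.62 ± 0.108 FPKM in the nucleus (limma adjusted p = 0.153). The RMST values may include reads from the abundant circRNA of that gene. Of 18 snoRNA host and cytoplasmic lncRNAs, 13 rose, SNHG3 fell (-0.94) and 4 were not called, against 6 higher and 4 lower after scaling (camera adjusted p = 0.0557). Examples were SNHG29 (2.15), SNHG16 (2.09), SNHG6 (1.87) and NORAD (0.87). Adjusted over the list alone, the calls in these lists numbered 6 and 15.

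CircRNAs were compared between cytoplasm and nucleus, the contrast that the series title concerns. The circRNA with the highest level, from exons 7 to 15 of RMST on chromosome 12 from 97492461 to 97561047, measured 44.9 ± 4.01 FPB in the cytoplasm, 19.98 ± 1.10 FPB in the nucleus and 72.7 ± 2.15 FPB in total RNA (log2 fold change 1.16 ± 0.07, limma adjusted p = 2.2e-07, and -0.03 after scaling). Other abundant circRNAs higher in the cytoplasm came from MAN1A2 (1.67), SMARCA5 (1.41), the readthrough locus MSANTD3-TMEFF1 (1.54), RIMS1 (1.26), CDYL (0.61, and -0.57 after scaling) and CAMSAP1 (0.42, and -0.76 after scaling). The circRNA of HIPK3, a single-exon ring on chromosome 11 from 33286413 to 33287511, rose by 1.77, and that of ZNF609, on chromosome 15 from 64499293 to 64500166, by 1.26. CDR1-AS, a circRNA known for its binding sites for miR-7, on chromosome X from 140783176 to 140784660, measured 6.70 ± 0.165 FPB in the cytoplasm and 5.43 ± 0.571 FPB in the nucleus and did not pass (0.30, limma adjusted p = 0.0855). After scaling it lay on the other side, at -0.87, and was not called by limma either.

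The largest cytoplasmic excess belonged to the circRNA of SCLT1, exons 6 to 9, on chromosome 4 from 128992167 to 129003876. It had 72 and 86 reads in the cytoplasmic libraries, 0 in both nuclear libraries and 0 and 42 in the total-cell libraries. Counting error alone would put the cytoplasmic level at least 17.1-fold above the nuclear floor of 3 reads per library, averaged over both libraries. The total-cell replicates, at 0 and 42 reads, differed beyond counting error, so this is not a firm lower bound. Next came circRNAs of PSD3 (3.26), PAK3 (2.93), RSRC1 (2.58), ATRNL1 (2.18), ZMYM4 (1.92), QKI (1.82) and BMPR2 (1.82). PSD3 and PAK3 had 0 reads in nucleus replicate 1 and 12 and 4 reads in nucleus replicate 2. The circRNA of ZNF91, on chromosome 19 from 23358430 to 23362725, went the other way with 3 reads over the cytoplasmic and 22 over the nuclear libraries, a nuclear-to-cytoplasmic ratio of 11.1 (95% exact interval 3.35 to 58.2, counting error only). Its total-cell level, 10.5 ± 2.995 FPB, was above both fractions. Also lower in the cytoplasm, and named after their values were seen, were circRNAs of VCAN (0.0748 against 0.572 FPB) and POMT1 (0.274 against 0.943 FPB).

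Of 914 tested circRNAs, 282 were higher in the cytoplasm and 3 lower (limma, adjusted p below 0.05), and edgeR on the recovered reads called 278 and 2, of which 263 were shared with limma. Scaled by the mRNA factors, 0 were higher and 1 (ZNF91) lower by limma, with 106 at an unadjusted p below 0.05. Leaving out cytoplasm replicate 1 or 2 left 16 and 15 calls, 1 of them lower in each case, and without nucleus replicate 2 also 1 was lower. The spread of each circRNA on its own gave 26 calls.

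The 3 RNA classes were set side by side to ask how their localization compared. The median log2(cytoplasm/nucleus) was 0.82 ± 0.13 for mRNAs, 0.26 ± 0.07 for lncRNAs and 1.05 ± 0.14 for circRNAs (SD between the replicate medians, libraries matched by number, n = 2). For lncRNAs it was 0.09 over the 1834 without exonic overlap with a protein-coding gene, a split made after seeing the data, and 0.42 over the 2372 with it. Summed over each class, the cytoplasmic values were 3.43 times the nuclear FPKM for mRNAs, 1.72 times for lncRNAs and 2.23 times the nuclear FPB for circRNAs. The entry AL355075.4, which overlaps RPPH1 and is uncertain, alone measured 13419.7 FPKM in the cytoplasm and 1257 FPKM in the nucleus. All lncRNA entries summed to 58026.8 and 63982.2 FPKM in the cytoplasmic and 36948.9 and 33845.6 FPKM in the nuclear libraries. That entry thus made up a large part of the lncRNA excess. FPKM, and FPB as read here, are scaled within each library, so the sums do not measure the RNA that a compartment held. After scaling to one median, the class medians were 0.03, -0.005 and 0.13. mRNAs and lncRNAs were each scaled by the medians of their own class, and circRNAs by the mRNA factors. The cytoplasmic factors were 0.79 and 0.84 for mRNAs and 1.01 and 1.09 for lncRNAs. The nuclear ones were 2.01 and 1.72 for mRNAs and 2.03 and 1.75 for lncRNAs. The scaling itself thus fixed the medians of mRNAs and lncRNAs, and the scaled values do not compare these classes. A pseudocount of 0.1 FPKM raised the lncRNA median to 0.66. The order of mRNAs and circRNAs was not fixed, since with pseudocounts of 0.1 FPKM and 0.369 FPB, which raise the mRNA and lower the circRNA ratios, their medians were 1.18 and 0.72, while edgeR on the recovered reads gave a circRNA median of 1.23. The FPKM and FPB tables were normalized separately, so no test between classes was made.

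**Figure D3:**
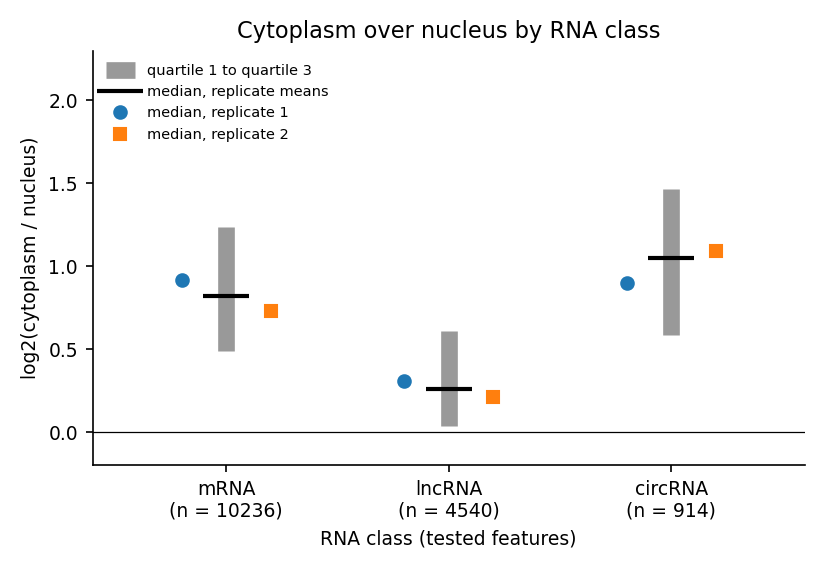
Median (black bar) and quartiles (grey) of log2(cytoplasm/nucleus) over tested mRNAs, lncRNAs and circRNAs, with the medians of replicate 1 (circles) and replicate 2 (squares). Replicate medians were 0.92 and 0.73 for mRNAs, 0.31 and 0.21 for lncRNAs and 0.90 and 1.10 for circRNAs.

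The series title concerns A-rich circRNAs, so the adenosine content of the spliced sequence was compared with localization over the 895 tested circRNAs with a reconstructed sequence. CircRNAs with more A had a higher cytoplasm-to-nucleus ratio. The median log2(cytoplasm/nucleus) was 0.73 in the fifth with the least A, 1.02, 1.11 and 1.16 in the groups between and 1.19 in the fifth with the most. Across circRNAs, which are not independent replicates, Spearman's rho was 0.217 and Pearson's r 0.210 (two-sided permutation p = 1e-05 for both, the smallest 100000 permutations can give; adjusted p = 1.2e-05 and 1.5e-05 over the 6 features tested). Without the 2 circRNAs farthest from the median A content r was 0.220. The size of rho depended on the filter, with 0.0553 over 30237 circRNAs without one and 0.332 over the 230 above a filter 3 times higher, and the longest run of A in place of A content gave 0.0855 (permutation p = 0.0105). Replicate 1 gave rho = 0.203 and replicate 2 rho = 0.150. The fifth with the most A did not pass camera's test against the other circRNAs (p = 0.0689, and p = 0.132 with an estimated correlation).

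Other features of the same circRNAs ran in parallel. The rho was 0.226 for U, -0.254 for G and -0.214 for C, and with the G and C fraction held, an alternative chosen after seeing the data, the relation with A was 0.01 (permutation p = 0.806). Exon number gave rho = 0.179 (adjusted permutation p = 1.2e-05), with medians of 0.93 for 123 single-exon circRNAs, 1.03 for 469 circRNAs of 2 or 3 exons and 1.18 for circRNAs with 4 or more. In replicates 1 and 2 rho was 0.1855 and 0.1008 for exon number, 0.2142 and 0.1384 for U, -0.2451 and -0.1638 for G and -0.2008 and -0.1348 for C. Spliced length gave rho = 0.03 (permutation p = 0.344) but r = -0.147 (permutation p = 2e-05).

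**Figure D4:**
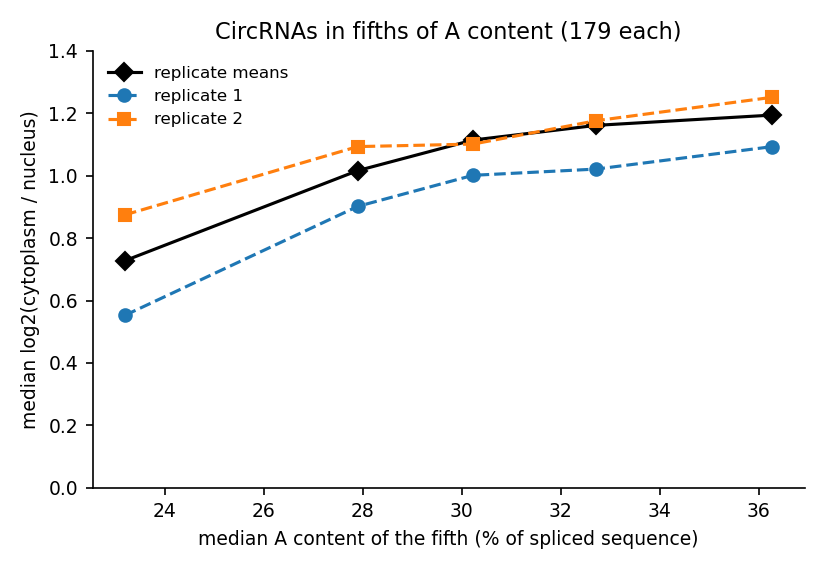
Median log2(cytoplasm/nucleus) of circRNAs in groups of equal size by A content (179 each), for the replicate means (diamonds), replicate 1 (circles) and replicate 2 (squares), against the median A content of the group in percent. The medians of the replicate means went from 0.73 at 23.2% A to 1.19 at 36.3% A.

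CircRNAs were also compared with the mRNA of the same host gene. The libraries were made from total RNA, so reads within a ring may also count in the FPKM of its host gene. The comparison is therefore not one of circular with linear RNA alone. Over 625 host genes the circRNA lay above its mRNA in 64.5%, with medians of 1.02 and 0.66 and a median difference of 0.31. That share depended on the pseudocounts, since with 0.1 FPKM and 0.369 FPB, an alternative chosen after seeing the data that raises the mRNA and lowers the circRNA ratios, it was 32.0% with a median difference of -0.29, and the FPKM and FPB tables were normalized separately. Host genes with a more cytoplasmic mRNA had only slightly more cytoplasmic circRNAs (across genes, which are not independent replicates, rho = 0.084, two-sided permutation p = 0.0359; r = 0.102, permutation p = 0.0101), and rho was 0.143 with the other pseudocounts. With replicate 1 alone, that is without replicate 2, rho was 0.0504 (permutation p = 0.208) and the circRNA lay above its mRNA in 52.8% of hosts.

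Comparison of the fractions with total-cell RNA showed that many transcripts, as deposited, measured higher in total RNA than in either fraction. MALAT1 reached 640 ± 102 FPKM in total RNA, a log2 fold change of -4.29 for cytoplasm and -3.30 for nucleus against total (limma adjusted p = 6.3e-06 and 7.1e-06). MAP1B reached 199.8 ± 19.96 FPKM, SPTBN1 26.0 ± 2.37 FPKM against 2.56 ± 0.0547 and 6.25 ± 0.643 FPKM in cytoplasm and nucleus, and PRRC2C 21.7 ± 1.48 FPKM against 2.65 ± 0.160 and 5.51 ± 0.522 FPKM. MIAT measured 16.8 ± 2.62 FPKM, ZNF462 21.9 ± 1.05 FPKM and CDR1-AS 29.1 ± 1.30 FPB in total RNA. The histone mRNA H4C11 ran the other way, with 400.6 ± 26.0 FPKM in total RNA and 1711 FPKM in the cytoplasm.

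For mRNAs, 3105 were higher and 4498 lower in the cytoplasm than in total RNA, and 67 were higher and 9697 lower in the nucleus (limma). After scaling the splits were 4907 and 3786, and 4123 and 3869. The 67 became 38 without nucleus replicate 2 and 42 without total replicate 1. For lncRNAs they were 573 and 2624 for cytoplasm and 36 and 3995 for nucleus, against 1769 and 1452 and 1552 and 1224 after scaling, and the 36 became 20 without nucleus replicate 2. For circRNAs, 1 was higher and 39 lower in the cytoplasm, and 1 was higher and 570 lower in the nucleus. The single higher one, named after its value was seen, was in both cases the CAMSAP1 circRNA on chromosome 9 from 135850137 to 135866536, with 0 reads in total RNA. Those 0 reads allow 0.369 and 0.296 FPB, above the 0.247 FPB of nucleus replicate 1 (0.543 FPB in replicate 2), so a nuclear excess was not resolved at this depth, while the cytoplasmic libraries had 0.748 and 0.720 FPB. After scaling by the mRNA factors, 0 circRNAs were higher and 6 lower in the cytoplasm (78 at an unadjusted p below 0.05) and 3 higher and 15 lower in the nucleus. The 3, named after their values were seen, were circRNAs of FAT1 and CREB5 and the abundant CAMSAP1 circRNA from 135881633 to 135883078, which is not the one with 0 reads in total RNA. The summed counts of circRNA calls fell whichever library was left out, which also lowers the residual degrees of freedom. The small counts of higher circRNAs were not stable and rose when a total-cell library was left out. There were 5 calls (without cytoplasm replicate 2) to 18 calls (without total replicate 1) for cytoplasm, also 11 without cytoplasm replicate 1 and 10 without total replicate 2, and for nucleus 363 and 370 calls without total replicate 1 or 2 and 498 and 458 without nucleus replicate 1 or 2.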

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

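The tests of scaling, leakage and short genes in this part were chosen only after the result was seen.

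Outside the mRNA and lncRNA comparisons, the table of all gene types held small structural RNAs at high levels. RN7SK, the 7SK RNA that binds and restrains a transcription elongation factor, on chromosome 6 from 52995621 to 52995948, measured 72462 ± 50.3 FPKM in the cytoplasmic libraries, 14918 ± 964 FPKM in the nuclear libraries and 25958 ± 744 FPKM in total RNA (SD, n = 2). RPPH1, the RNA subunit of RNase P, on chromosome 14 from 20343075 to 20343407, measured 12851 ± 1834 FPKM in the cytoplasm, 1204 ± 15.3 FPKM in the nucleus and 3971 ± 687 FPKM in total RNA. Both are known as nuclear RNAs, and of the comparisons only the alternative with all gene types used these values. RPPH1 shares its position with the lncRNA AL355075.4, which was in the lncRNA comparison with 13419.7 ± 1914 FPKM in the cytoplasm and 1257 ± 16.1 FPKM in the nucleus.

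The excess of both RNAs in the cytoplasmic libraries was weighed against 3 technical explanations. A scale difference between the fraction libraries was predicted to put 7SK near the median mRNA, but RN7SK lay 1.46 above it on the log2 scale. A factor per library shifts 7SK and mRNAs together, so this distance cannot decide on the scale. It shows only that RN7SK lay further to the cytoplasmic side than the median mRNA. Leakage of all small nuclear RNAs was predicted to put the small Cajal body RNAs above the mRNA median. The median of 11 such genes lay at -3.13 relative to it and RMRP at -1.79. Over-representation of every short gene was predicted to put the snoRNAs above it, but their median over 236 genes lay at -1.39. Both types may start well below the mRNA median, so a partial leak or a weaker bias towards short genes could not be excluded. Shorter mRNAs did have higher cytoplasm-to-nucleus ratios (rho = -0.512 with exon length). Loss of only loosely bound nuclear particles into the cytoplasmic fraction may remain as a hypothesis, untested here, and no biological explanation was tested.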

How the results depend on the processing

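The alternatives without exonic overlap, with all gene types, with each feature's own spread, with the mean level or the G and C fraction held and with other pseudocounts for the host genes were chosen only after the result was seen. Where one replicate was left out, the lone library was assumed to vary like the other groups, and values that come from no test used the remaining replicate. Replicate numbers are shared in the labels, but replicate differences did not go together in all fractions (for mRNAs 0.01 for cytoplasm and nucleus, 0.15 for cytoplasm and total, 0.46 for nucleus and total, and for lncRNAs -0.12 for cytoplasm and nucleus), so the main fit did not take the numbers as pairs. Replicate medians, replicate correlations and the sign rule for naming matched libraries by number only as a convention. Their values would differ with another matching. With the replicate block 9361 mRNAs and 2092 lncRNAs were called between cytoplasm and nucleus, and no sum of calls moved by over 1.5 times. Against total RNA, 0 circRNAs were then higher and 46 lower in the cytoplasm, so the CAMSAP1 circRNA with no reads in total RNA was no longer called there. For circRNAs 2-fold changes, simulated on the scale with the pseudocount added, were recovered in 13.2% of cases. The part of depth in this was not separated from other spread between replicates. The causes of the changes below were not tested.

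Without a filter, with more genes tested, the calls were 11585 mRNAs between cytoplasm and total and 14927 between nucleus and total, and 6710 and 8013 lncRNAs. For circRNAs they were 12 between cytoplasm and nucleus, 9 between cytoplasm and total and 44 between nucleus and total. The lncRNAs without exonic overlap, a smaller set, gave 376, 1431 and 1632 calls in these comparisons. With each feature's own spread 1344 lncRNAs were called between cytoplasm and nucleus, and 26, 0 and 206 circRNAs in the 3 comparisons by limma, where the 0 for cytoplasm and total stands beside 144 at an unadjusted p below 0.05 and 60 by edgeR. Scaled to one median, 1, 6 and 18 circRNAs were called. Without the trend 156 circRNAs were called between cytoplasm and nucleus and 6 between cytoplasm and total, and with a larger pseudocount 68 between cytoplasm and total. Leaving out one library gave 1275 to 1705 lncRNAs between cytoplasm and nucleus, and 15 to 261, 5 to 18 and 363 to 498 circRNAs in the 3 comparisons.

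With an estimated correlation no list passed camera, with adjusted p = 0.433 for ribosomal protein, 0.281 for mitochondrially encoded, 0.488 for respiratory chain, 0.281 for histone, 0.908 for zinc finger, 0.908 for ER and secreted, 0.908 for detained-intron and 0.870 for long neuronal mRNAs. The medians of log2(cytoplasm/nucleus) without a filter were 0.37 for mRNAs, 0.0105 for lncRNAs and 0.24 for circRNAs. With the filter 3 times higher they were 1.14 for mRNAs and 0.61 for lncRNAs, and with the other pseudocounts 1.18, 0.66 and 0.72. The circRNA median ranged from 0.90 to 1.10 with one replicate left out. The relation with A content was 0.00824 with the G and C fraction held and 0.0553 without a filter, 0.332 with the filter 3 times higher and 0.0855 for the longest run of A. For the highest count of A in 20 nt it was 0.141. The relation with the host mRNA ranged from 0.0504 to 0.0795 with one replicate left out. It was 0.148 over 192 hosts with the filter 3 times higher and 0.143 with the other pseudocounts.

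Scaling to one median turned the sign of 19 named features called under at least one scaling and of the CDR1-AS circRNA (-0.87), called under neither. Besides the 19, 66 stayed on their side of the threshold, CDR1-AS among them, 22 kept their sign but no longer passed and 2 newly passed. The reversed values were -0.027 for the RMST, -0.76 for the CAMSAP1 and -0.57 for the CDYL circRNA, -0.14 for ZNF532, -0.94 for ZNF462, -0.14 for CALR, -1.08 for HSPA5, -0.97 for CANX, -0.30 for DDX5, -0.14 for DDX17, -0.009 for EGR1, -0.69 for JUN, -0.26 for DUSP1, -0.50 for AUTS2, -0.22 for CTNNA2, -0.13 for SOX2, -0.17 for DLX1, -1.02 for COL1A1 and -0.17 for DLX6-AS1.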

Other observations

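The test of one constant between the scales, the mixtures, the scaled counts above both fractions and the alternatives that held the G and C fraction or the mean level or had total RNA in the ratio were chosen only after the result was seen.

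Of 4 minor spliceosomal RNAs examined, RNU6ATAC lay at -0.34 relative to the mRNA median and the others above it, with RNU12 at 87.6 ± 7.09 FPKM in the cytoplasm and 27.9 ± 1.61 FPKM in the nucleus, RNU11 at 78.3 ± 1.04 and 32.1 ± 1.05 FPKM, and RNU4ATAC at 21.5 ± 0.690 and 8.38 ± 0.642 FPKM. The major spliceosomal RNA genes RNU1-4 and RNU4-2 lay below it, at -1.45 and -0.99 relative to the median, and of 98 tested snRNA genes 35 lay above and 63 below. SCARNA10 measured 108 ± 2.32 FPKM in the cytoplasm and 821 ± 103 FPKM in the nucleus, and SCARNA7 109 ± 3.51 and 598 ± 52.9 FPKM. RMRP, the RNA of RNase MRP, measured 6330 ± 945 FPKM in the cytoplasm and 12378 ± 1603 FPKM in the nucleus, the opposite direction to the related RPPH1. All 22 mitochondrial tRNA genes and both mitochondrial rRNA genes lay above the mRNA median. RN7SL1, the RNA of the signal recognition particle, lay at -0.07 relative to it. These are values, with no test of the difference between types.

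Exon length ordered the mRNAs in both ratios. From the fifth with the shortest exonic length (median 2008 nt) to the longest (median 10594 nt), the median log2(cytoplasm/nucleus) went from 1.31 to 0.46 and the median log2 of total over the mean of the fractions from 0.21 to 0.98. Both total-cell libraries exceeded all 4 fraction libraries for 5077 of 10236 mRNAs (49.6%) and 395 of 914 circRNAs (43.2%) as deposited, where libraries in random order give 6.67% and groups in random order with replicates kept together 33.3%. With the libraries scaled to one median (circRNAs by the mRNA factors) the counts were 3331 (32.5%) and 158 (17.3%), so the excess in number over the order of groups was present as deposited and not after scaling.

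The number of genes above both fractions depended on the scale. The SD of the log2 ratio over mRNAs was 5.01 times that between the total-cell replicates, against at most 2.46 times for the mixtures of both fractions that were computed. Mixtures alone thus did not reach the spread between genes. No constant was put into them, and with a pseudocount added a constant shifts genes of low and high level by different amounts. One constant together with a mixture was therefore not excluded. Under-representation of longer transcripts in both fractions needs a rise with length, and the relation was there (rho = 0.455 across mRNAs), so a length bias of the fraction libraries is a candidate explanation. A nuclear pool missing from both fractions, on top of length, stayed undecided. Among the mRNAs nearest in exon length, the 13 listed nuclear lncRNAs had a median percentile of 68.0. MALAT1 and MIAT lay at 100, but NEAT1 at 31.5, OIP5-AS1 at 24 and SOX2-OT at 10. SOX2-OT, LINC00632, SNHG14 and KCNQ1OT1, with 28876 to 91667 nt, shared the same median of their nearest mRNAs (1.228). The match in length was therefore not close for the longest lncRNAs, and the median percentile rests partly on them.

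The hypothesis that A-rich circRNAs were more nuclear in these cells was tested, since the series title concerns such circRNAs. The relation ran the other way, with rho = 0.150 in the lower of both replicates. A base-composition bias shared with mRNAs was predicted to give mRNAs the same sign, but their rho was -0.213 (-0.08 with exon length held). The mRNA ratio also fell with exon length (rho = -0.512), and circRNA levels rest on junction reads only. The sign over mRNAs therefore does not exclude a composition bias among circRNAs. Level does not account for it, since rho was 0.218 with the mean level held. The relation was not separable from base composition as a whole, with rho = 0.00824 once the G and C fraction was held, and against total RNA A content went with lower values in both fractions (rho = -0.317 for nucleus and -0.162 for cytoplasm).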
